A study of Homo sapiens with 6 samples.

How the data were processed

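The series holds 6 RNA-seq libraries of the human uveal melanoma line 92.1 in its cisplatin-resistant form, 3 with a BCAT1 hairpin and 3 with a control hairpin, both delivered by lentivirus. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, fragmented, copied into cDNA with dUTP in the second strand, and sequenced as paired-end reads on an Illumina NovaSeq instrument. Such libraries keep strand, but how strand was set in counting is not given in the sources used here. Selection by poly(A) tail makes levels of mRNAs without a tail, such as replication-dependent histones, depend on the selection. Samples were grouped by the genotype in the labels, and the replicate numbers come from the sample titles.

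The authors deposited 1 table of 31512 genes with an FPKM column per library (fragments per kilobase of transcript per 1e6 mapped fragments). Per the submitters' processing notes, fastp, HISAT2, StringTie and edgeR were used with the build GRCh38, and versions, settings and the annotation release are not given in the sources used here. The same table carries the authors' fold change as a ratio, its log2, and a p-value and q-value per gene, besides GO and KEGG terms. Their log2 fold change equalled the log2 ratio of the group mean FPKM within 1e-06 in 25503 of the 25503 genes with both means above 0. Genes at 0 in all 6 libraries are not listed. FPKM divides by transcript length and by the library's total, so a change in a few abundant transcripts moves the values of all others. The summed FPKM per library ran from 227633 to 268103. GO terms of 1898 genes and KEGG terms of 21 genes were masked in the table and are not used here.

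FPKM are not counts, so the count test planned as first choice (edgeR, with its TMM scaling and DESeq2 as alternatives) was not run, and the planned test for such values was used. It was limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), for genes with a mean of at least 0.5 FPKM over the 6 libraries, with shBCAT1 against shNC as the only term, two-sided, and Benjamini-Hochberg adjustment over the 13433 genes tested. A gene was called changed at an adjusted p below 0.05. Fold changes are on the log2(FPKM + 1) scale; folds of means are ratios of mean FPKM. Depth was estimated relative to one library from the spacing of values under 0.5 FPKM in genes with 1 annotated transcript; whole reads could not be recovered for most genes, so no counting intervals are given.

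Gene lists (35 lists, 807 symbols, 766 of them in the table) were fixed before the data were examined, for branched-chain amino acid, glutamate and 2-oxoglutarate metabolism, amino acid response and mTORC1, platinum transport and DNA repair, p53, apoptosis, cell cycle, melanocyte and uveal melanoma genes, signalling, lipid and energy metabolism, stress responses, immune genes, other cell types and RNA quality. Each was tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 35 lists, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance and does not compare it with other genes. With an estimated correlation, camera rests on the few residual degrees of freedom of these libraries, so few lists can pass whatever their correlation. GO and KEGG terms with 15 to 300 tested genes were tested with camera against the annotated tested genes (10032 for GO and 5128 for KEGG). The named genes followed a rule fixed before the data were examined. It took BCAT1, then the 10 largest rises and 10 largest falls among genes with a symbol, an adjusted p below 0.05, a mean of at least 1 FPKM in the higher group and groups that did not overlap, then from each list up to 2 rises and 2 falls past the threshold, or the 2 members with the highest mean where none passed. The rule gave 118 genes besides BCAT1, of which the text prints examples; some named genes are not reported here.

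The fit was tested on simulated data with 200 changed genes among 13433 in 20 simulations of the shBCAT1 against shNC comparison. It recovered 84.7% of genes changed by 1 and 48.9% of genes changed by 0.5 on the log2 scale, with the right sign in 100% and 4.62% false calls among the calls. A list of 30 genes shifted by 0.24 was found in 20 of 20 simulations, and 0 of 680 unchanged lists were called. With 3 libraries per group, small changes are therefore found only in part. The noise was drawn independently for each gene and library, so the simulations held neither correlated genes nor a library that lies apart. They do not measure how often lists are falsely called in these data.

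GENCODE release 29 (GRCh38) gave coordinates, transcript length, GC content and 3′ UTRs. Length and GC content were those of the longest annotated transcript of each gene, which need not be the one expressed. It matched 29227 of the 31512 gene identifiers (92.75%), and 13049 of the tested genes had a length and GC content. The alternatives set out before the data were seen were a pseudocount of 0.1, no filter, stricter thresholds, leaving out each library in turn, a replicate block, and other settings of the list and term tests. Median-of-ratios scaling, scaling to the total without mitochondrial transcripts, a correction of each library for GC content and transcript length with splines of 4 degrees of freedom, and limma array weights were chosen after seeing the data. So were a scan of 7-base words in 3′ UTRs and a search for blocks of neighbouring genes, both described among the other observations. The word scan covered 8183 coding genes with a mean of at least 3 FPKM and a 3′ UTR, took the longest annotated 3′ UTR of each, removed trends with its length, its GC content and expression, and compared genes with and without each of 16084 words found in at least 50 genes. Tested with 20 planted words that shifted their genes by -0.15 on the log2 scale, it ranked the planted word first in 20. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for tables and scans, and matplotlib 3.10.9 for figures.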

Results

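RNA abundance was measured by poly(A)-selected, strand-marked RNA sequencing in 92.1 cells, an established human uveal melanoma line, in a form made resistant to the platinum drug cisplatin. The cells carried a lentiviral short hairpin RNA against BCAT1 (shBCAT1, 3 libraries) or a control hairpin (shNC, 3 libraries). BCAT1 is the cytosolic transaminase that moves the amino group of leucine, isoleucine and valine onto 2-oxoglutarate and so forms glutamate. The deposited table gave FPKM for 31512 genes, of which 13433 had a mean of at least 0.5 FPKM and were tested. Read totals were not given in the sources used here. From the spacing of the lowest FPKM values, the depth of the libraries relative to shBCAT1 replicate 1 was 1.03 and 1.07 for shBCAT1 replicates 2 and 3 and 1.155, 1.03 and 1.175 for shNC replicates 1 to 3, but the absolute depth is unknown. The labels do not say whether the 3 libraries of a group came from separate cultures or from separate hairpins, so the p-values measure the spread between these libraries, which may be technical.

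BCAT1 itself (ENSG00000060982, chromosome 12, positions 24810022 to 24949459 on the minus strand of GRCh38) was read first. It stood at 2.07 ± 0.27 FPKM in shBCAT1 (SD, n = 3) and at 7.33 ± 1.13 FPKM in shNC (SD, n = 3), a 3.54-fold lower mean. Its 3 shBCAT1 values were 1.77, 2.30 and 2.14 FPKM, and its 3 shNC values were 7.28, 8.48 and 6.21 FPKM. The log2 fold change was -1.43 (SE 0.118) on the log2(FPKM + 1) scale used throughout, which understates the change of low genes (limma-trend, adjusted p = 0.00117).

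The comparison of shBCAT1 with shNC asks which transcripts differ once BCAT1 is knocked down in the resistant cells. On the log2(FPKM + 1) scale, the largest falls were in SPP1 (osteopontin, a secreted phosphoprotein), at 6.45 ± 1.01 against 63.6 ± 1.72 FPKM, a 9.86-fold lower mean, and in MGP (matrix Gla protein, an inhibitor of calcification), at 0.830 ± 0.0817 against 11.1 ± 1.00 FPKM, a 13.4-fold lower mean (SD, n = 3 in each group). Their limma log2 fold changes were -3.13 (SE 0.104) and -2.73 (SE 0.0801), both with an adjusted p of 8.6e-05. ANXA1 (annexin A1) fell from 8.71 ± 0.225 to 1.21 ± 0.130 FPKM, and ERBB3, a receptor for neuregulins, from 11.2 ± 0.681 to 2.69 ± 1.22 FPKM. GNAT3, SERPINI1, FGF9, HSPB2 and STMN3 also fell, with log2 fold changes of -2.65, -2.06, -2.01, -1.89 and -1.88. By the ratio of means FGF9, at 0.494 ± 0.104 against 5.03 ± 0.465 FPKM, was 10.2-fold lower, which is more than SPP1. Among the rises, TLE1, a transcriptional corepressor, stood at 4.17 ± 0.125 against 1.10 ± 0.0977 FPKM, HABP4 at 17.4 ± 1.10 against 6.78 ± 0.201 FPKM, and SPHK1, which makes sphingosine 1-phosphate, at 6.30 ± 0.265 against 2.26 ± 0.0532 FPKM. EEF1A2, TNFRSF19, PAG1, ENO3 and FLNC rose with log2 fold changes of 1.47, 1.27, 1.23, 1.23 and 1.17. SLC7A5P1, TRIM39-RPP21 and PMF1-BGLAP share sequence with another gene, and their values are uncertain for that reason. SLC7A5P1, a pseudogene of the amino acid transporter SLC7A5, was at 7.92 ± 1.67 against 1.03 ± 0.553 FPKM. The readthrough gene TRIM39-RPP21 was listed at 0 in the 3 shNC libraries and at 2.80, 0.943 and 1.05 FPKM in shBCAT1. The readthrough gene PMF1-BGLAP was at 0.723 ± 0.391 against 5.28 ± 3.35 FPKM, and its call was lost without shBCAT1 replicate 1 or 3 or shNC replicate 1 or 2 (adjusted p = 0.0502, 0.0709, 0.108 and 0.0886).

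**Figure D1:**
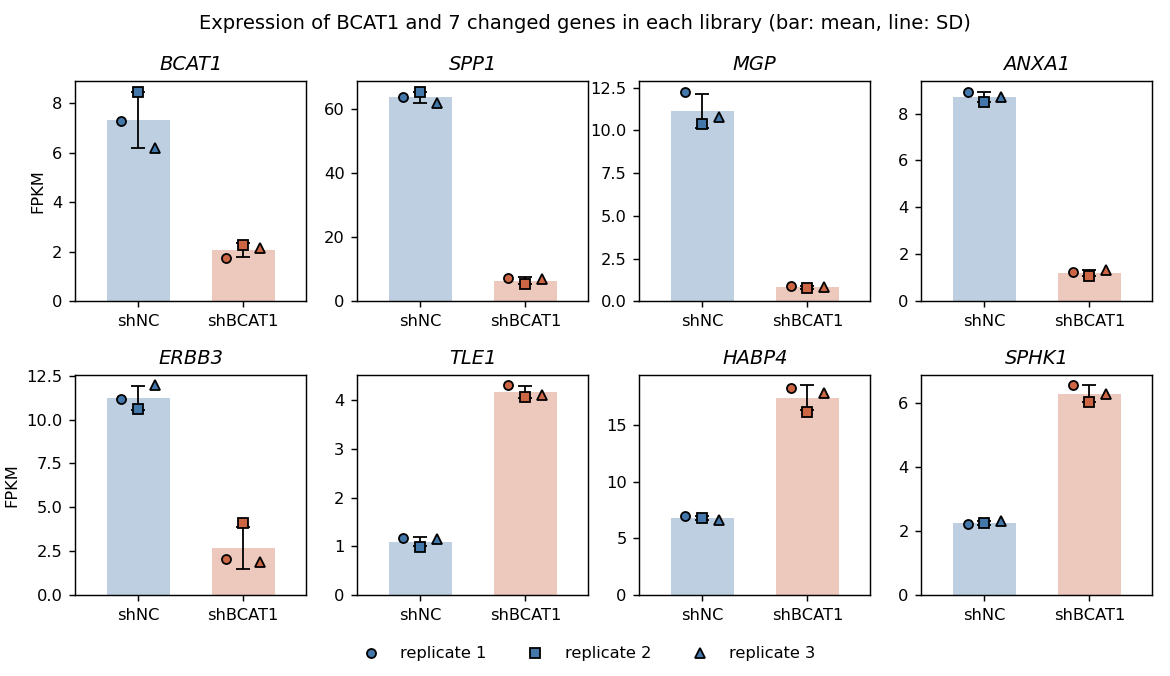
FPKM on the vertical axis of each panel, from 0, for BCAT1 and 7 of the genes with the largest changes in the 3 shNC libraries (blue) and the 3 shBCAT1 libraries (orange). Bars are means, lines are SDs, and symbols are the replicates; for SPP1 the shBCAT1 libraries sit between 5.30 and 7.22 FPKM and the shNC libraries between 61.8 and 65.3 FPKM, while for ERBB3 shBCAT1 replicate 2 (4.10 FPKM) lies above the other 2 shBCAT1 libraries (2.06 and 1.91 FPKM).

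Over all tested genes, 3557 differed between the groups by limma-trend at a Benjamini-Hochberg adjusted p below 0.05, 1965 higher and 1592 lower in shBCAT1. On the log2(FPKM + 1) scale, which shrinks the changes of low genes, 88 of them had an absolute log2 fold change of at least 1, 28 higher and 60 lower. In 6627 genes (49.3%) the 3 libraries of one group lay above the 3 of the other, where chance gives 10%. The count depended on which libraries entered. It was 5866 without shBCAT1 replicate 2 and 1533, 1570 and 1766 without shNC replicate 1, 2 and 3. For single genes, 3 against 3 libraries cannot give an exact two-sided permutation p below 0.1, so the calls rest on the spread that limma shares across genes.

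The shBCAT1 libraries were not alike. Over the tested genes, replicates 1 and 3 correlated at r = 0.992 across genes, and replicate 2 with them at 0.980 and 0.979, while the shNC libraries correlated at 0.992 to 0.994 (genes are not independent replicates). On the first principal component, which held 56.8% of the variance, all 3 shBCAT1 libraries lay opposite the shNC libraries. On the second, with 22.7%, shBCAT1 replicate 2 scored 19.0 and replicates 1 and 3 scored -14.5 and -15.5.

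**Figure D2:**
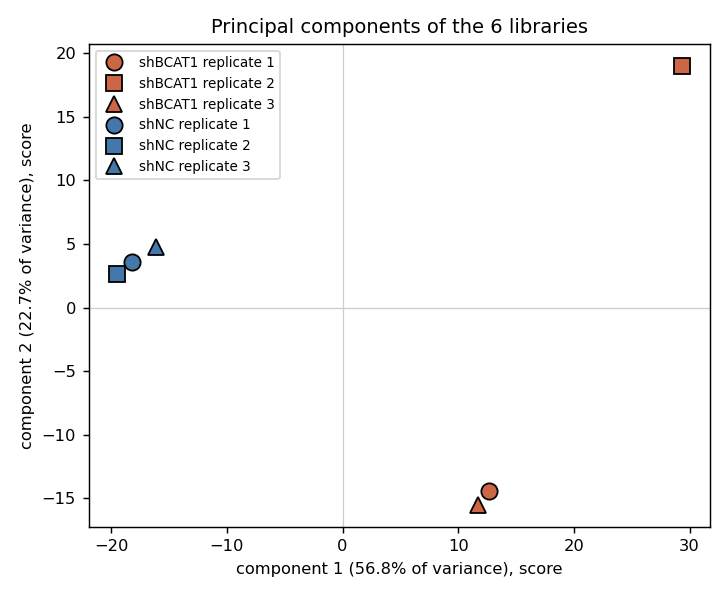
Scores of the 6 libraries on the first (horizontal) and second (vertical) principal components of log2(FPKM + 1) over the 13433 tested genes, with 56.8% and 22.7% of the variance. The shBCAT1 libraries (orange) score 11.7 to 29.4 on the first component and the shNC libraries (blue) -19.5 to -16.1, and shBCAT1 replicate 2 lies apart from the other shBCAT1 libraries on the second.

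Among genes of cell division, more members passed the threshold as higher than as lower. Of 30 tested G2/M and mitosis genes, 14 rose and 1 fell, with a median log2 fold change of 0.24 (camera adjusted p = 9.5e-05, and adjusted p = 0.278 with an estimated correlation). CENPF, a kinetochore protein, was at 40.3 ± 5.87 FPKM in shBCAT1 against 23.5 ± 1.29 FPKM in shNC, and TPX2, a spindle assembly factor, at 66.6 ± 8.03 against 39.6 ± 0.533 FPKM. PTTG1 (securin), which holds back sister chromatid separation, was the member that fell, from 114 ± 1.92 to 89.3 ± 5.58 FPKM. Its call was lost without shNC replicate 1 or 3 (adjusted p = 0.0583 and 0.0530). Of 30 tested G1/S and DNA replication genes, 11 rose and 2 fell, with a median of 0.14 (camera adjusted p = 0.0076, and adjusted p = 0.559 with an estimated correlation). The replication licensing factor CDT1 rose with a log2 fold change of 0.83 (SE 0.138). Against the direction of the list, thymidylate synthase (TYMS) fell from 118.8 ± 0.724 to 85.5 ± 4.71 FPKM and the polymerase clamp PCNA from 327 ± 7.07 to 268 ± 4.23 FPKM, the latter not past the threshold without shBCAT1 replicate 1 or without shNC replicate 1, 2 or 3 (adjusted p = 0.0587, 0.0899, 0.0678 and 0.0615). Adjusted over the list alone, 15 G2/M genes rose and 1 fell, and 11 G1/S genes rose and 2 fell. Leaving out 1 library gave 7 (without any 1 shNC library) to 21 (without shBCAT1 replicate 2) changed G2/M genes and 6 (without shNC replicate 1 or 2) to 21 (without shBCAT1 replicate 2) changed G1/S genes, and both lists stayed past the camera threshold.

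All 25 tested ribosomal protein transcripts had a negative log2 fold change, 8 past the threshold (10 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 9.5e-05, and adjusted p = 0.685 with an estimated correlation). RPLP1 of the ribosomal stalk stood at 150.4 ± 12.7 against 211 ± 15.6 FPKM, a call lost without shNC replicate 1 (adjusted p = 0.0546). RPL4 stood at 224 ± 37.8 against 312 ± 1.29 FPKM, a call lost without shBCAT1 replicate 1 or any 1 shNC library (adjusted p of 0.0512 and 0.0989 to 0.107). The libraries differed within shBCAT1. Ribosomal protein transcripts made up 5.95% of the summed FPKM in shBCAT1 replicate 2, 7.26% and 7.31% in replicates 1 and 3, and 7.39% to 8.11% in shNC. Leaving out 1 library gave between 1 (without shNC replicate 1) and 20 (without shBCAT1 replicate 2) changed members, and the list stayed past the camera threshold.

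The 13 mRNAs encoded by the mitochondrial genome had negative log2 fold changes in all cases, with a median of -0.59 (-0.40 without shNC replicate 2 and -0.74 without shNC replicate 3), and 3 of them passed the threshold (camera adjusted p = 0.0028, adjusted p = 0.685 with an estimated correlation, and 0.0871 by fry). Adjusted over the list alone, 10 passed. MT-CO2, a subunit of cytochrome c oxidase, stood at 2370 ± 429 against 3992 ± 877 FPKM, and MT-ND6, a subunit of complex I, at 583 ± 108 against 1026 ± 271 FPKM. Both calls were lost without shBCAT1 replicate 1 or 3 and without shNC replicate 1 or 2, the adjusted p then running from 0.0517 to 0.0979 for MT-CO2 and from 0.0577 to 0.101 for MT-ND6. MT-CO2 was also lost without shNC replicate 3 (adjusted p = 0.0638). Mitochondrial transcripts made up 15.5%, 12.3% and 15.1% of the summed FPKM in shBCAT1 replicates 1 to 3 and 16.9%, 22.7% and 16.4% in shNC. No member passed without shBCAT1 replicate 1 or 3, without shNC replicate 1 or 2, or with a correction for GC content and transcript length, and 1 passed without shNC replicate 3, while the list itself stayed past the camera threshold. Among 32 nuclear genes of oxidative phosphorylation, 3 rose and 7 fell, and the list did not pass (camera adjusted p = 0.116). COX6C, of complex IV, fell from 36.7 ± 0.715 to 23.6 ± 0.656 FPKM, whereas SDHA, of complex II, rose from 18.2 ± 0.310 to 27.5 ± 2.16 FPKM. This list had 18 changed members without shBCAT1 replicate 2 and 5 without shNC replicate 1.

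**Figure D3:**
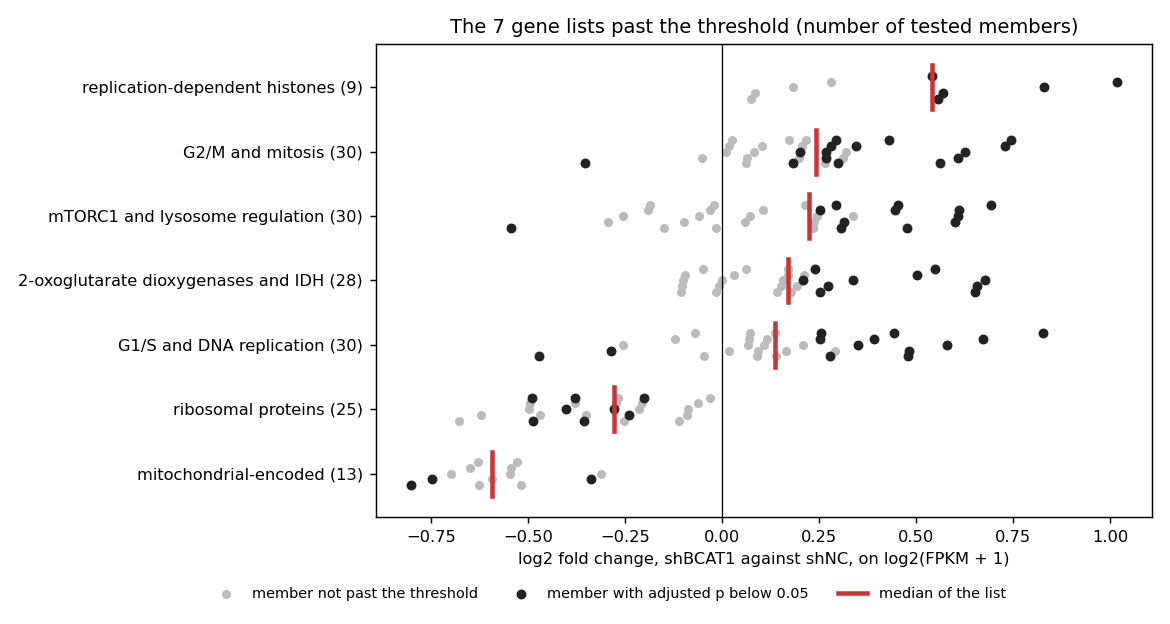
Log2 fold change of each tested member (horizontal axis, shBCAT1 against shNC on log2(FPKM + 1)) for the 7 lists past the camera threshold, with the number of tested members in brackets. Black points passed an adjusted p of 0.05, grey points did not, and red lines are list medians, from -0.59 for mitochondrially encoded mRNAs to 0.54 for replication-dependent histones.

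Branched-chain amino acid genes did not move as a group. Of 30 tested members, BCAT1 included, 6 rose and 4 fell, with a median log2 fold change of 0.03 and a mean of -0.02 (camera adjusted p = 0.774). SLC7A8, an exporter and exchanger of neutral amino acids, rose from 81.3 ± 2.46 to 128.4 ± 19.9 FPKM, and ALDH6A1, a valine catabolism enzyme, from 2.75 ± 0.0854 to 4.33 ± 0.193 FPKM. In the list of amino acid and ATF4 response genes, 9 of 30 rose and 2 fell (camera adjusted p = 0.169). PCK2 rose from 5.36 ± 0.274 to 9.61 ± 0.842 FPKM, and CHAC1, which degrades glutathione, fell from 8.44 ± 0.409 to 3.79 ± 1.22 FPKM. Glutamate and glutathione genes split into 4 higher and 6 lower of 22 (camera adjusted p = 0.906), with GGT1 at 9.54 ± 1.09 against 5.64 ± 0.129 FPKM and GSTO1 at 33.4 ± 4.43 against 51.3 ± 1.92 FPKM. Of 28 genes for isocitrate dehydrogenases and for dioxygenases that use 2-oxoglutarate, 10 rose and none fell (11 and 0 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.0028, and adjusted p = 0.559 with an estimated correlation). The histone demethylases KDM2A and KDM6B stood at 10.9 ± 0.886 against 6.44 ± 0.280 FPKM and at 7.37 ± 0.499 against 4.31 ± 0.0656 FPKM. A correction for GC content and transcript length ended the call of this list, with a median of 0.07 and an adjusted p of 0.176. Leaving out any 1 library other than shBCAT1 replicate 2 left 6 changed members. Of 30 genes of mTORC1 and lysosome regulation, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.0382, and adjusted p = 0.559 with an estimated correlation). SESN2, an inhibitor of mTORC1, rose from 4.38 ± 0.381 to 7.70 ± 0.634 FPKM, and GPNMB, a glycoprotein of lysosomes and melanosomes, from 249.8 ± 1.12 to 383 ± 41.5 FPKM. This list was not past the threshold without shNC replicate 1 (adjusted p = 0.0536), with the GC and length correction (0.0815), with median-of-ratios scaling (0.0561) or with array weights (0.0643). Its median was 0.12 without shBCAT1 replicate 2. It had 5 changed members without shNC replicate 1 or 2, 7 without shNC replicate 3 and 16 without shBCAT1 replicate 2. Adjusted over the list alone, 7 branched-chain amino acid genes rose and 4 fell, 12 amino acid and ATF4 response genes rose and 2 fell, and 6 glutamate and glutathione genes rose and 7 fell. Without shBCAT1 replicate 2 these lists had 16, 19 and 14 changed members, and without shNC replicate 1 they had 6, 4 and 4.

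None of the lists chosen for the response to cisplatin passed the camera threshold with all libraries. Member counts are to be read against 3557 called of all 13433 tested genes, 1965 higher and 1592 lower. By fry, which does not compare a list with other genes, drug transport, p53 targets and the unfolded protein response passed. Their fry adjusted p were 0.0091, 0.0435 and 0.0284, and the other lists of this paragraph did not pass by fry. Of 11 genes of drug transport and metallothioneins, 4 rose and 1 fell (camera adjusted p = 0.0764, and 0.0423 at its lowest when 1 library was left out). LRRC8A, a subunit of the volume-regulated anion channel that also carries cisplatin, rose from 12.6 ± 0.531 to 21.6 ± 2.56 FPKM, and the metal-binding MT2A rose with a log2 fold change of 0.83 (SE 0.153), a call lost without shNC replicate 1 (adjusted p = 0.0510). Nucleotide excision and crosslink repair genes gave 4 higher and 1 lower of 30 (camera adjusted p = 0.143), with SLX4 at 3.89 ± 0.424 against 2.13 ± 0.0838 FPKM. Homologous recombination genes gave 5 higher and none lower of 25 (camera adjusted p = 0.143), and BRCA1 rose from 5.30 ± 0.235 to 8.16 ± 0.555 FPKM. Among 24 p53 targets, 4 rose and 6 fell (camera adjusted p = 0.486), with TNFRSF10B (death receptor 5) at 34.6 ± 1.82 against 25.7 ± 1.59 FPKM and PHLDA3 at 7.06 ± 0.192 against 10.6 ± 0.344 FPKM. Apoptosis regulators gave 3 higher and 3 lower of 25 (camera adjusted p = 0.906). The BH3-only gene BMF fell from 27.2 ± 1.49 to 15.1 ± 1.80 FPKM. NRF2 targets (6 higher, 4 lower of 20, adjusted p = 0.676), ferroptosis regulators (2 higher, 4 lower of 19, adjusted p = 0.906) and the unfolded protein response (4 higher, 0 lower of 22, adjusted p = 0.371) did not pass either, and no NRF2 target passed without shNC replicate 1. Adjusted over the list alone, higher and lower members numbered 6 and 1 for drug transport, 4 and 0 for excision repair, 4 and 0 for homologous recombination, 4 and 6 for p53, 3 and 3 for apoptosis, 9 and 5 for NRF2, 3 and 5 for ferroptosis, and 1 and 0 for the unfolded protein response. Without shBCAT1 replicate 2 these lists had 8, 13, 9, 16, 13, 15, 10 and 12 changed members. Leaving out another library lowered the number to 3 for drug transport, 4 for apoptosis and 1 for the unfolded protein response (without shNC replicate 1), 4 for p53 and 2 for ferroptosis (without shNC replicate 2), 3 for homologous recombination (without shNC replicate 3) and 2 for excision repair (without shBCAT1 replicate 1).

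Lineage and signalling genes of the melanoma cells also went both ways, and no list of this paragraph passed the camera threshold with all libraries. By fry, YAP/TAZ targets and antigen presentation passed (fry adjusted p = 0.0091 each). So did epithelial-mesenchymal transition and matrix, melanocyte and interferon response genes (fry adjusted p = 0.0138, 0.0435 and 0.0496). The other lists of this paragraph did not pass by fry. Of 22 melanocyte lineage and pigmentation genes, 4 rose and 6 fell (camera adjusted p = 0.549), with the endothelin receptor EDNRB at 54.3 ± 5.07 against 76.2 ± 2.20 FPKM. Of 10 tested neural crest and dedifferentiation genes, 4 rose and 3 fell (camera adjusted p = 0.846), with a positive median and a negative mean. L1CAM was at 1.24 ± 0.215 against 0.413 ± 0.0522 FPKM. MAPK output genes gave 5 higher and 5 lower of 20 (camera adjusted p = 0.766). EGR1 rose from 3.02 ± 0.228 to 6.79 ± 0.849 FPKM, while RASGRP3, an activator of RAS signalling in GNAQ and GNA11 mutant uveal melanoma, fell from 30.9 ± 0.489 to 18.8 ± 3.65 FPKM. Uveal melanoma driver and prognosis genes gave 4 higher and 4 lower of 21 (adjusted p = 0.766), with ROBO1 at 6.18 ± 0.118 against 3.13 ± 0.0797 FPKM and ID2 at 44.6 ± 3.11 against 65.7 ± 3.12 FPKM. Of 19 YAP/TAZ targets 5 rose and 1 fell (adjusted p = 0.143), and of 20 genes of epithelial-mesenchymal transition and matrix 7 rose and 4 fell (adjusted p = 0.371). CCN1 rose from 4.01 ± 0.135 to 6.83 ± 0.0754 FPKM, the membrane protease MMP14 rose from 139 ± 7.48 to 235 ± 6.22 FPKM, and TWIST2 fell from 3.42 ± 0.255 to 1.69 ± 0.252 FPKM. Fatty acid synthesis and desaturation genes gave 5 higher and 1 lower of 19 (adjusted p = 0.169), with FASN at 66.7 ± 10.4 against 35.9 ± 1.88 FPKM and its activator SREBF1 at 14.1 ± 2.45 against 7.65 ± 0.426 FPKM. Cholesterol synthesis genes split into 4 higher and 6 lower of 23 (adjusted p = 0.906), with INSIG1 at 16.8 ± 2.05 against 11.4 ± 0.173 FPKM and MSMO1 at 16.4 ± 0.118 against 24.2 ± 1.27 FPKM. Glycolysis and hypoxia genes gave 1 higher and 3 lower of 27 (adjusted p = 0.906), where the mitophagy receptors BNIP3L and BNIP3 stood at 19.4 ± 4.30 against 37.8 ± 0.839 FPKM and at 6.40 ± 1.25 against 11.2 ± 0.257 FPKM. Median and mean also differed in sign for glycolysis, cholesterol synthesis and ferroptosis. Interferon response (1 higher, 1 lower of 14), NF-kB and inflammatory genes (1 higher, 0 lower of 6) and antigen presentation (3 higher, 1 lower of 16) had adjusted p of 0.486, 0.421 and 0.248. Without shBCAT1 replicate 2 the number of changed members rose to 14 each for the melanocyte, MAPK, uveal melanoma and cholesterol lists, to 17 for epithelial-mesenchymal transition, to 12 for YAP/TAZ, to 11 for glycolysis, to 10 for fatty acid synthesis, to 4 for interferon response and to 2 for NF-kB. Without shNC replicate 1 the YAP/TAZ, glycolysis, MAPK and NF-kB lists had 3, 2, 6 and 0 changed members. Without shNC replicate 2 the melanocyte, cholesterol, epithelial-mesenchymal transition and antigen presentation lists had 3, 3, 4 and 1.

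Markers of other cell types were mostly below the filter. Of the immune markers, 3 were tested and 2 rose (camera adjusted p = 0.0581). The call of CORO1A, 1 of these 2, was lost without shBCAT1 replicate 1 or 2 or any 1 shNC library (limma adjusted p of 0.0595 to 0.159). The lysosomal glycoprotein CD68, which melanoma cells also express, stood at 43.9 ± 6.21 against 19.7 ± 0.404 FPKM. Of the fibroblast markers, 3 were tested and 2 rose (adjusted p = 0.0732), with FBLN1 at 48.2 ± 6.14 against 32.3 ± 0.185 FPKM. The call of the other, COL1A1, was lost without shNC replicate 1, 2 or 3 (limma adjusted p = 0.0888, 0.0776 and 0.0559). The immune and fibroblast lists passed in some settings that left out 1 library, their lowest adjusted p being 0.0216 and 0.0390. Of 2 epithelial markers, ESRP1 fell from 10.4 ± 1.36 to 5.22 ± 0.473 FPKM and KRT18 stood at 3.56 ± 0.472 against 2.55 ± 0.237 FPKM, a call lost without shBCAT1 replicate 3 or any 1 shNC library (adjusted p = 0.0902 and 0.0741 to 0.123). The list's adjusted p was 0.788. The 1 endothelial marker tested, EMCN, was at 15.7 ± 3.54 against 18.1 ± 0.984 FPKM and did not pass. Among replication-dependent histone genes, whose mRNAs normally lack a poly(A) tail, 5 of 9 tested rose and none fell, with a median of 0.54 (camera adjusted p = 0.0076, and adjusted p = 0.559 with an estimated correlation). H2BC5 stood at 14.2 ± 1.26 against 6.50 ± 0.434 FPKM. Leaving out 1 library left 2 changed histone genes, or 6 without shBCAT1 replicate 2.

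A search over the annotation terms carried by the deposited table gave 35 of 1227 GO terms past the camera threshold, 16 with higher and 19 with lower genes in shBCAT1, and 7 of 286 KEGG pathways, 1 higher and 6 lower. None passed with an estimated correlation, where the leading GO and KEGG terms had adjusted p of 0.971 and 0.835. That setting has few degrees of freedom with 6 libraries. The G2/M list had an estimated correlation of 0.0038, below the preset 0.01, yet its camera adjusted p went from 9.5e-05 to 0.278. A loss in that setting alone therefore neither upholds nor undoes a call. The estimated correlations differed between the lists that passed. They were 0.666 for ribosomal proteins, 0.836 for mitochondrially encoded mRNAs and 0.217 for histones. For G1/S, 2-oxoglutarate and mTORC1 genes they were 0.077, 0.041 and -0.015. Where the correlation lies far above the preset, as for ribosomal proteins and mitochondrially encoded mRNAs, the camera p-values at the preset are likely too small. The lower GO terms were led by cytoplasmic translation, with 18 of 83 genes lower and none higher (adjusted p = 1.3e-05). Mitochondrial respiratory chain complex I assembly (16 of 61 lower, 3 higher, adjusted p = 0.0113) and mitochondrial translation (14 of 93 lower, 5 higher, adjusted p = 0.0081) were also among them. The higher GO terms were led by regulation of small GTPase mediated signal transduction (23 of 66 higher, 6 lower, adjusted p = 0.00089), microtubule organizing center (22 of 50 higher, 2 lower, adjusted p = 0.0015) and anchoring junction (58 of 173 higher, 15 lower, adjusted p = 0.0018). The ribosome pathway led KEGG (27 of 134 lower, 1 higher, adjusted p = 1.6e-07), followed by oxidative phosphorylation (25 of 120 lower, 7 higher, adjusted p = 0.0097). With the GC and length correction, 15 GO terms and 1 KEGG pathway passed. Leaving out 1 library gave 4 KEGG pathways without shBCAT1 replicate 2, 12 without shBCAT1 replicate 3 and 2 without shNC replicate 3.

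The authors' deposited table marked 640 genes as changed, 315 higher and 325 lower, which are the genes with a q-value below 0.05 and an absolute log2 fold change of at least 1 in that table. Of these, 297 were above the expression filter and 343 were below it. Of the 297, 285 (96.0%, exact 95% binomial interval 93.0 to 97.9) were past the limma threshold here with the same sign. The interval treats genes as independent, which they are not. Both fold changes come from the same FPKM values, so agreement in sign was close to fixed in advance. The log2 fold changes of the authors' deposited table, which are ratios of mean FPKM with no pseudocount, had a Spearman correlation of 0.985 and a Pearson correlation of 0.805 with those used here across the 13433 genes, which are not independent replicates.

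Across the tested coding genes, the log2 fold change rose with transcript length and with GC content (Spearman correlation of 0.251 and 0.248 across 11340 genes). The fifth of the genes with the shortest transcripts had a median of -0.12 and the fifth with the longest 0.09. Of 46 named genes that fell and had a 3′ UTR, 12 held one of 4 short sequences that marked lower genes in particular shBCAT1 libraries, against 32.9% of genes not past the threshold. The longest annotated 3′ UTR of FGF9, ERBB3, TYMS, BNIP3, BNIP3L, BMF and RPLP1 held one, and so did that of named genes that rose, among them TLE1, TNFRSF19, PAG1, MMP14, KDM2A, SESN2, L1CAM and INSIG1.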

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

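The scalings, the GC and length correction, the array weights, and the other pseudocount and missing filter for the annotation terms were chosen after seeing the data, and the other alternatives before. BCAT1 stayed lower and past the threshold in all 13 alternatives. The count of changed genes, 3557 as reported, ran from 1533 to 5866 when 1 library was left out, from 1533 to 1766 without an shNC library and at 5866 without shBCAT1 replicate 2. It was 7251 with array weights, which gave shBCAT1 replicate 2 a weight of 0.0975, 1361 at an adjusted p below 0.01, and 88 when a log2 fold change of at least 1 was also required. The missing filter, the pseudocount, the scalings and the GC and length correction gave 2441 to 3721, and 3553 of the 7251 and 3538 of the 5866 genes were among the reported calls with the same sign. With the GC and length correction 2643 of 3360 calls were among the reported 3557, over 13049 tested genes. The shared calls were 3193 of 3616 with median-of-ratios scaling and 3299 of 3721 without mitochondrial transcripts. They were 2152 of 2441 without the filter and 3485 of 3500 with the pseudocount. Scaling without mitochondrial transcripts gave 64.1% higher among the called genes, against 55.2%. Of the lists, 7 passed as reported, 0 with an estimated correlation and 16 by fry. GO terms past the threshold, 35 as reported, were 15 with the GC and length correction and 0 with an estimated correlation. KEGG pathways, 7 as reported, were 2 to 12 when 1 library was left out, 2 without the filter, 4 without mitochondrial transcripts in the total, 1 with the GC and length correction and 0 with an estimated correlation. Of the 118 named genes besides BCAT1 none changed sign in any of the 13 alternatives. Calls were lost for 28 to 33 of them without an shNC library, for 11, 1 and 9 without shBCAT1 replicate 1, 2 and 3, for 26 without the filter, for 4 to 6 with a scaling or the correction, and for none with the pseudocount of 0.1 or array weights. Fewer libraries and more tested genes can each cost calls in the leave-one-out and unfiltered settings. Leaving out shBCAT1 replicate 2 also removes 1 library but raised the count of changed genes, so that count did not follow the number of libraries alone. The rise does not tell why leaving out an shNC library lowered it. The causes of the moves were not tested. Replicate numbers did not pair the libraries, since deviations from the group means correlated at -0.035, -0.093 and -0.144 between same-numbered libraries and none matched its own number best. A replicate block gave 1973 genes, 11 KEGG pathways and 21 lost calls among the named genes. Another TMM or size factor scaling, DESeq2 and edgeR were not run, since FPKM are not counts. Without read totals, the limit that depth sets on low genes is unknown.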

Other observations

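The word scan, the share of genes with leading words and the search for gene blocks were designed after the data were seen, and the tests of sequencing depth and of chance scatter were also chosen after their results were seen. The word scan followed a look at the genes that set shBCAT1 replicate 2 apart, and its prediction was written before any scan value was seen. The joined 8-base words, their values per library and their positions in BCAT1 were added after the scan, the leading words were picked on the same genes in which their share is given, and the blocks were seen over all genes before the test on every other gene. The patterns weighed were chosen with the data in view. A rise of mitotic genes was weighed at first, and its tests were dropped after their results were seen, to make room for the blocks. The G2/M list median was 0.24 as reported, 0.27 with the GC and length correction and 0.20 without shBCAT1 replicate 2. Neither that library nor bias that follows the longest annotated transcripts therefore accounted for it. Neighbouring genes moved together in places. By chromosome, the lowest medians of log2 fold change were on chromosome 15 (-0.13, with 32 genes higher and 118 lower of 412 tested), chromosome 2 (-0.12, 61 higher and 165 lower of 838) and chromosome 10 (-0.10, 49 higher and 120 lower of 478). The highest were on chromosome 16 (0.11, 163 higher and 27 lower of 646), chromosome 9 (0.07, 116 higher and 27 lower of 519) and chromosome 17 (0.05, 195 higher and 82 lower of 820). The GC and length correction changed the order at the top, with chromosomes 13, 8 and 9 highest at 0.06 each and chromosomes 16 and 17 at 0.05 and 0.03, and left chromosomes 15 and 2 lowest at -0.16 and -0.10. In the block with the lowest median, at 119.9 to 133.3 Mb of chromosome 10 on GRCh38, all 19 genes that had no part in choosing the block were below 0, with a median of -0.36, and 17 of them were called changed. The 3 windows with the highest medians were all on chromosome 17, and their 57 genes left out had a median of 0.21, or 0.15 with the GC and length correction, against 0.39 in the genes that chose them.

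Library shBCAT1 replicate 2 lay apart from the other 2 shBCAT1 libraries. Lower depth and a mislabelled or unaffected library are argued against. Its depth relative to their mean was 0.995, and it carried a median share of 0.953 of their shift from shNC over the 1059 genes called without it at an absolute log2 fold change of 0.5 or more. The GC and length correction removed 11.7% of its squared distance from them, which argues against bias that follows the longest annotated transcripts. Bias that follows other expressed transcripts stays open. A candidate explanation is that this library holds a different BCAT1 hairpin, because a hairpin can also lower mRNAs whose 3′ UTR matches its seed and each hairpin would mark its own genes. Genes with the word CCTACCA were lower in replicate 2 than in replicates 1 and 3 (absolute z = 14.34, 617 genes), and genes with CACTGAA lower in replicates 1 and 3 than in shNC (z = -14.2, 1329 genes), against a highest absolute z of 6.05 in 4 comparisons of libraries within groups that leave this library out. C-rich words found in no BCAT1 transcript also passed 6.05, with higher genes in replicate 2. CCCACCC had z = 7.04 against replicates 1 and 3 and 7.13 against shNC. CCCCTCC and CACCCCC had z = 6.59 and 6.19 against shNC. Not all words past that value therefore go with a hairpin seed. Against shNC, genes with TCACTGAA averaged -0.168, -0.013 and -0.167 in replicates 1, 2 and 3 relative to other genes, and genes with CCTACCAA 0.022, -0.231 and 0.026. Both words occur in 7 of 10 BCAT1 transcripts, in coding exon 7 (chromosome 12, 24842128 to 24842135, GRCh38) and coding exon 6 (24849921 to 24849928) of a transcript with 11 exons. Of all 8-base words 15.2%, and of the scanned 7-base words 44.0%, lie anywhere in at least 1 BCAT1 transcript, UTRs included. The match of a single word to BCAT1 is therefore weak evidence. Shares for coding exons, or for a match of both words, were not computed.

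If so, part of the falls may be effects of hairpin seeds rather than of BCAT1. Most lower genes held none of the 4 leading words. Of 1445 genes lower in shBCAT1 with a 3′ UTR, 39.0% held one of the 4 leading words (CACTGAA, TCACTGA, CCTACCA or CTACCAA), against 32.9% of genes not past the threshold and 28.7% of genes higher, an excess of 6.09 percentage points over the genes not past the threshold. Among the 497 genes lower by at least 0.5 on the log2 scale, 44.3% held one. These shares were not adjusted for 3′ UTR length. They also leave out other words that marked lower genes. Examples are ACTACCA (z = -8.70, replicate 2 against replicates 1 and 3) and ACACTGA (z = -8.25, replicates 1 and 3 against shNC). The part of the falls due to seeds is therefore unknown. Among named genes that fell, 12 of 46 held one, besides BCAT1, which is no larger share than among genes not past the threshold. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05; the real split, 1 of 10, gave 3557 genes and the highest of the others 1.

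The lower ribosomal protein list, with a median of -0.28 and a call lost with an estimated correlation (adjusted p = 0.685), was weighed against 3 technical explanations. Its estimated correlation of 0.666 lies far above the preset 0.01, so the camera p-values given here, at the preset, are likely too small. After the GC and length correction the median was -0.25 (camera adjusted p = 0.00033, 9 of 25 lower). The correction used each gene's longest annotated transcript, 1962 bases for RPLP1 and 2769 bases for RPL4. Where the expressed transcript is shorter, it cannot remove a length bias, so such bias stays open. The share of the total taken by mitochondrial transcripts as the whole cause is argued against by a median of -0.23 after scaling without them (camera adjusted p = 9.3e-05, 6 lower). Over all alternatives that left out 1 library, the adjusted p ran from 6.0e-07 to 0.00055. Without shBCAT1 replicate 2 the median was -0.19 (adjusted p = 6.0e-07, 20 lower), so the direction did not need that library but the size was 0.685 of that with all libraries, and how much of the size belongs to that library alone cannot be told apart from the common fall with 3 libraries. An effect of the BCAT1 knockdown stays open and was not tested apart from the hairpins.

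Blocks of neighbouring genes lower in shBCAT1 may reflect a difference in DNA copy number between the transduced cell populations, a hypothesis that RNA alone does not test. In the 3 windows with the lowest medians, chosen on every other gene (2 on chromosome 10, at 102.7 to 113.9 and 119.9 to 133.3 Mb, and 1 on chromosome 15, at 74.6 to 78.9 Mb), the 57 genes left out had a median of -0.308, below the -0.112 that was the lowest in 100 shuffles of the genes, which argues against chance scatter of single genes. The GC and length correction left a median of -0.259 and leaving out shBCAT1 replicate 2 one of -0.287. This argues against that library, and against bias that follows the longest annotated transcripts, as the whole cause. The chromosome 15 window held up least, with a median of -0.10 in its 19 genes left out, and the window at 102.7 to 113.9 Mb of chromosome 10 went from -0.25 to -0.16 without shBCAT1 replicate 2, which alone had -0.35. A regional effect on chromatin or a clonal difference unrelated to the hairpins stays open.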
